A study of Mus musculus with 8 samples.

How the data were processed

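Total RNA from 8 samples of bone marrow-derived dendritic cells, 1 per condition, was hybridised to Affymetrix mouse arrays of 45101 probe sets. Per the labels, 100 ng of total RNA per sample was labelled in a protocol with successive rounds of reverse transcription. The deposited values were intensity signals on a linear scale, computed with MAS5 per the submitters' processing notes. The version of MAS5 was not given in the sources used here. Each deposited column had a 2% trimmed mean of 100, so the authors had scaled every array to one target. Scanner files and detection calls were not used here.

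Signals were multiplied so that every array had a 2% trimmed mean of 500, a factor of 5 for each, and values under a floor of 100 were raised to it before log2 was taken. Of the probe sets, 64 were controls, 34945 carried 1 gene symbol, 932 several and 9160 none. Symbols were updated by Entrez identifier with a table of RefSeq genes on the mouse assembly GRCm38.p6 where possible, which covered 34741 probe sets. Each gene was represented by the probe set with the highest mean signal over all 8 arrays, which left 18193 genes, 9010 of them with more than 1 probe set. Probe sets with several symbols or none were not used in the comparisons of genes.

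There were 11 comparisons of a pair of arrays. Because each condition had 1 array, no test, standard error or p-value could be computed, and a gene counted as higher or lower if its signals were at least 2-fold apart (a log2 of 1). Genes at the floor on both arrays were given no fold, and those at the floor on 1 array were given a bound. The median log2 fold of each of 32 gene lists, 22 of cellular programmes and 10 of markers of cell types and sex, was placed among 10000 random lists with members matched on mean expression in 20 bins (seed 1). The percentile describes these arrays and is not a test, since genes on an array are not independent samples. The lists were interferon-stimulated genes, type I and III interferons, inflammatory cytokines, chemokines, dendritic cell maturation, class I and class II antigen presentation, the integrated stress response, endoplasmic reticulum chaperones and the unfolded protein response, eIF2alpha kinases and phosphatase subunits, translation initiation factors, cytosolic ribosomal proteins, apoptosis regulators, double-stranded RNA sensing, NF-kB feedback and inhibitors of Toll-like receptor signalling, immediate early genes, proliferation, cholesterol synthesis, lysosome, NRF2 targets, heat shock, and glycolysis and HIF targets. The marker lists covered conventional and plasmacytoid dendritic cells, macrophages and monocytes, granulocytes and their precursors, mast cells and basophils, B cells, T and NK cells, erythroid cells, stromal cells and sex-linked genes. There were 352 pairs of a list and a comparison, in 1 of which, the B cell markers with lipofected pIC 16 h against lipofectamine only, 0 genes were measured. A list's measured genes are those above the floor on at least 1 array of the pair. A member at the floor on 1 array is thus measured only through the array where it is higher. Of 9 interferon genes named on the array, 2 to 6 were measured in a comparison. Some genes belonged to more than 1 list.

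Genes were named by a rule. In each comparison these were the 6 largest increases and the 6 largest decreases among genes above the floor on both arrays, the 4 largest increases and 2 largest decreases among genes at the floor on 1 array, and up to 4 members of each list with the largest fold. Always included were Ppp1r15a, Atf4, Ddit3, Atf3, Eif2ak2, Ifnb1, Il6, Il12b, Tnf, Il1b, Il10, Cxcl10, Cd86 and Ccr7. The 100 genes measured only by probe sets of the type that may cross-hybridise within gene families were not ranked. The groups, comparisons, scaling, floor, threshold, gene lists, naming rule and the first 6 alternative settings were chosen before the data were examined.

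Those 6 alternatives were the values as deposited, quantile normalization over the 8 arrays, floors of 50 and 200, the mean over all probe sets of a gene, and leaving out probe sets that may detect several transcripts or genes. Using the lipofectamine only 16 h array as the reference for soluble pIC 16 h was added after seeing the data. A value counted as unmoved if it stayed within 1.5-fold of the main one.

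The rule was tested on simulated data, a pair of arrays with 18193 genes and noise with a standard deviation of 0.17 in log2, the spread of genes with signals above 1000 on the closest pair of arrays. It found 1 of 50 genes set 1.5-fold apart, 22 of 50 set 2-fold apart and 50 of 50 set 3-fold apart. Dimmer genes may be noisier than that, so the simulation does not give the share of unchanged genes called in the data. Of 100 lists of 30 unshifted genes, 96 lay inside the middle 95% of random lists. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.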

Results

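Gene expression was measured in dendritic cells grown from the bone marrow of C57BL/6 mice, cells that take up antigen and present it to T cells. The cells had been activated with lipopolysaccharide (LPS), a component of bacterial cell walls sensed by Toll-like receptor 4. They then received polyinosinic-polycytidylic acid (pIC), a synthetic double-stranded RNA that mimics viral RNA. It was given either in soluble form in the medium or lipofected, that is, carried into the cells by the transfection reagent lipofectamine. The 8 arrays were labelled no LPS at 0 h, LPS alone at 4 h and 16 h, LPS with soluble pIC at 4 h and 16 h, LPS with lipofected pIC at 4 h and 16 h, and LPS with lipofectamine only at 16 h. The labels do not say whether the hours count from LPS or from pIC, nor how long LPS was given before pIC, so the times are used as labels only. Each condition had 1 array and no replicates, so no error, test or p-value accompanies any value, and the number of arrays limits the precision of every fold. A gene is called higher or lower where its signals on a pair of arrays were at least 2-fold apart, which is a rule of size and not a test.

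Between 9657 genes (LPS 4 h) and 10318 genes (no LPS) of the 18193 measured lay above the signal floor of 100 on an array, or 53.1% to 56.7%. Probe sets near the 5′ and 3′ ends of actin differed by a log2 of −0.23 to −0.10 and those of Gapdh by 0.30 to 0.37, so the arrays were alike in these pairs. They were not alike in the pair for 18S ribosomal RNA, where the 5′ signal ranged 10.9-fold, from 3297 on the array labelled LPS 16 h to 35820 on LPS 4 h, and the 3′ signal 1.41-fold. Malat1, a nuclear RNA chosen after its values were seen, had its lowest signal on LPS 4 h (949) and its highest on soluble pIC 16 h (3961). The closest pair of arrays were lipofected pIC 16 h and lipofectamine only 16 h, with 51 genes at least 2-fold apart. The next closest were those labelled LPS 16 h and lipofected pIC 4 h, with 76 genes apart, although their labels shared neither the time nor the presence of pIC. By contrast, 1604 to 2300 genes separated the array labelled LPS 16 h from the other 16 h arrays. Among the 4 h arrays, soluble pIC was nearer to no LPS (1027 genes apart) than to LPS alone (2837 genes). Values for these arrays are therefore given under the labels they carry.

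**Figure D1:**
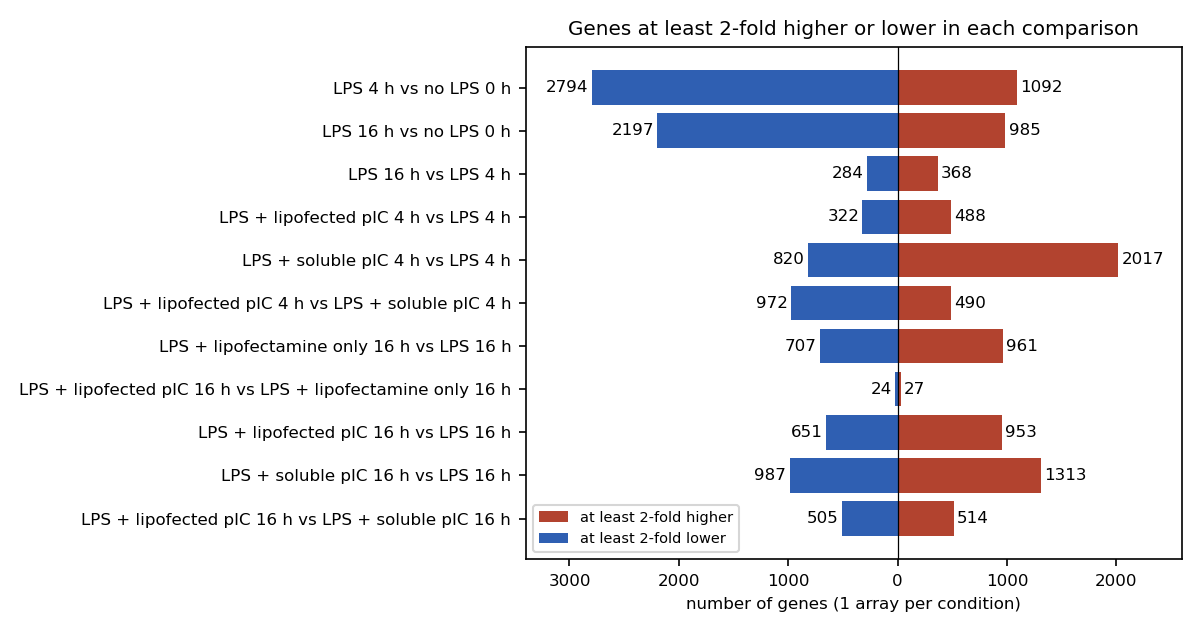
Number of genes at least 2-fold higher or lower (bars) in each of the 11 comparisons of a pair of arrays, with 1 array per condition. The counts run from 51 genes in all for lipofected pIC 16 h against lipofectamine only to 3886 for LPS 4 h against no LPS.

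The comparison of LPS 4 h with no LPS asked how dendritic cells responded to LPS alone. The only array without LPS was labelled 0 h, so here and for LPS 16 h the effect of LPS was not separated from that of time. Whether the arrays labelled LPS 4 h and soluble pIC 4 h carry each other's labels also stays open, as described further below. Genes for cytokines, chemokines, interferon-stimulated antiviral proteins and co-stimulatory molecules were higher after LPS, and genes for DNA replication and mitosis were lower. Il6, a proinflammatory cytokine, was 328-fold higher, with a signal of 122 without LPS and 40004 with it. Cxcl10, an interferon-inducible chemokine that draws T cells, was 269-fold higher. Ifit1, an antiviral protein that binds foreign RNA, was 232-fold higher, and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 173-fold higher. Il12b, the subunit shared by the cytokines IL-12 and IL-23, was at the floor without LPS and at least 350-fold higher with it.

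Of 18 measured inflammatory cytokine genes, 17 were higher, 0 lower and 1 neither. Tnf was 50.8-fold and Il1b 61.7-fold higher, and Il10, an anti-inflammatory cytokine, was at least 19.3-fold higher. Chemokines gave 17 higher, 0 lower and 2 neither of 19, among them Cxcl9, another interferon-inducible chemokine, at least 130-fold higher. All 35 interferon-stimulated genes measured were higher, with a median log2 fold of 4.39, above all 10000 random gene lists of matched expression. Only 2 of the type I and III interferon genes were measured, and 1 was higher, Ifnb1 (interferon beta), by at least 7.14-fold to a signal of 714. Sensors and adaptors of double-stranded RNA gave 15 higher, 1 lower and 3 neither of 19. They included Irf7, a transcription factor for interferon genes (74.3-fold), Dhx58, which encodes the sensor LGP2 (24.7-fold), Zbp1 (22.8-fold) and Ifih1, which encodes MDA5 (21.0-fold). Eif2ak2, which encodes the RNA-activated kinase PKR, was 9.54-fold higher. These named genes also belong to the interferon-stimulated list, so the counts of the lists overlap.

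Genes of dendritic cell maturation gave 18 higher, 0 lower and 2 neither of 20. Cd40, a co-stimulatory receptor, was 79.2-fold higher, Cd86, a ligand of CD28, 7.75-fold, and Ccr7, the receptor that guides dendritic cells to lymph nodes, 11.0-fold. In class I antigen presentation 8 of 13 genes were higher and 0 lower, including Nlrc5, a transactivator of class I genes (12.2-fold), and Tap1, a peptide transporter (5.18-fold). Class II presentation gave 0 higher and 1 lower of 13. The list of NF-kB subunits, feedback inhibitors and targets gave 18 higher and 0 lower of 19, such as Nfkbiz (27.8-fold), Acod1, the enzyme of itaconate synthesis (25.7-fold), and Tnfaip3, which encodes the deubiquitinase A20 (16.4-fold). Apoptosis regulators gave 9 higher and 3 lower of 23. Casp4, a sensor of cytosolic LPS, was 17.7-fold higher, Cflar, an inhibitor of caspase-8, 8.87-fold higher, and Bcl2 5.49-fold lower.

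The integrated stress response is the programme set off when phosphorylation of eIF2alpha slows translation. Of 38 measured genes of it, 7 were higher, 4 lower and 27 neither after LPS, with a median of 0.15 at percentile 99.9 of random lists. Those random lists had a median of −0.37, so the high percentile does not by itself mean that the genes rose. Ppp1r15a, which encodes GADD34, the subunit that targets a phosphatase to eIF2alpha, was 4.70-fold higher (531 to 2494). Atf3, a stress-induced transcription factor, was 5.26-fold higher and Slc7a11, a cystine transporter, 6.01-fold higher. Under the threshold were Atf4, the main transcription factor of the response (1.52-fold), and Ddit3, which encodes the proapoptotic factor CHOP (1.69-fold). Kinases and phosphatase subunits of eIF2alpha gave 4 higher and 3 lower of 11, with Eif2ak4, the amino acid sensing kinase GCN2, at least 4.98-fold lower. Translation initiation factors gave 1 higher and 7 lower of 35. Eif4ebp2, a repressor of cap-dependent initiation, was 3.90-fold lower and Eif1a was 2.68-fold higher. Cytosolic ribosomal proteins gave 1 higher and 1 lower of 43, endoplasmic reticulum chaperones 2 higher and 0 lower of 27, and heat shock genes 3 higher and 0 lower of 13, led by Hspa1b (11.9-fold) and Hspa1a (11.4-fold).

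Proliferation genes were 24 lower, 0 higher and 3 neither of 27, with a median of −2.04 that lay below all 10000 random lists. Mcm2, a subunit of the replicative helicase, was at least 9.48-fold lower, Aurkb, a mitotic kinase, 9.47-fold, and Cdc20, an activator of the anaphase-promoting complex, 6.31-fold (4597 to 728). Lysosomal genes gave 1 higher and 3 lower of 20 with a median of −0.43 (percentile 0.07), cholesterol synthesis 2 and 4 of 18, antioxidant targets of NRF2 3 and 3 of 15, glycolysis and HIF targets 2 and 2 of 19, and immediate early genes 5 and 4 of 17. The genes with the largest decreases included Tmem154 (31.1-fold), Slc43a2, an amino acid transporter (21.7-fold), Dna2, a nuclease of DNA replication (18.1-fold), and St6gal1, a sialyltransferase (at least 29.1-fold).

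Markers of other cell types moved alongside these groups. Macrophage and monocyte markers gave 4 higher and 5 lower of 19. Ccr2, the monocyte chemokine receptor, was 13.1-fold lower (10696 to 820) and Mrc1, the mannose receptor, 3.25-fold lower, whereas Cd14, a co-receptor for LPS, was 4.98-fold higher. Conventional dendritic cell markers gave 2 higher and 6 lower of 14, with Irf8 7.37-fold higher and Cd209a 6.16-fold lower. Granulocyte markers gave 1 and 3 of 15, mast cell markers 1 and 0 of 8, plasmacytoid dendritic cell markers 2 and 3 of 7, and stromal markers 1 and 0 of 12. Few markers of lymphoid and erythroid cells were measured at all, namely 2 for B cells (0 higher, 1 lower), 3 for T and NK cells (2 and 1) and 1 for erythroid cells (1 and 0). Of 3 sex-linked genes 0 were higher and 1 was lower.

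By this rule 1092 genes were higher and 2794 lower of the 10833 above the floor on at least 1 array of the pair, and the median of all genes was −0.37. Quantile normalization gave 1356 higher and 1775 lower, raised the share of higher genes from 28.1% to 43.3% and brought the median to −0.13.

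The array labelled LPS 16 h was also compared with no LPS. The interferon-stimulated genes were again higher throughout, 35 of 35 with a median of 4.32, and 11 of 14 measured cytokine genes were higher. Il6 was 90.1-fold higher than without LPS, Cxcl11, a chemokine of the same family as Cxcl10, at least 53.7-fold, and Ifnb1 at least 20.4-fold. Inflammatory cytokines gave 11 higher and 0 lower of 14, chemokines 13 and 0 of 19, maturation genes 18 and 0 of 20, and type I and III interferons 5 and 0 of 6. Proliferation genes gave 0 higher and 25 lower of 27. Genes of the integrated stress response split evenly, with 6 higher and 6 lower of 36, the latter including Yars, a tyrosyl-tRNA synthetase (4.72-fold), and Slc7a5, an amino acid transporter (3.98-fold). Hspa1b was 26.0-fold higher. Macrophage and monocyte markers gave 2 higher and 7 lower of 18. In all 985 genes were higher and 2197 lower of 10828, with a median of −0.33 over all genes. Quantile normalization gave 1167 and 1536, moved the share of higher genes from 31.0% to 43.2% and the median to −0.17.

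The labelled times with LPS alone were compared by setting the array labelled LPS 16 h against LPS 4 h. Most inflammatory cytokine genes and 9 of 19 chemokine genes were lower on the array labelled 16 h, most measured interferon genes were higher, and interferon-stimulated genes were level. Il1a, a proinflammatory cytokine, was 28.9-fold lower (11564 to 401), Cxcl1, a neutrophil chemokine, 59.8-fold lower (22318 to 373), and Il10 at least 19.3-fold lower. Cytokines gave 0 higher and 11 lower of 18, chemokines 0 and 9 of 19, and the NF-kB feedback list 0 and 7 of 19. Interferons gave 5 higher and 0 lower of 6 measured, led by Ifna2 (at least 8.49-fold), Ifna4 (at least 5.05-fold) and Ifnb1 (2.85-fold). Of the 9 named on the array, those at the floor with LPS 4 h could be measured only where they were higher. None of the 35 interferon-stimulated genes was 2-fold apart, and their median was 0.00. Proliferation genes had a median of 0.64, above all random lists, with 2 higher and 0 lower of 27. Ccnd1, which encodes cyclin D1, was 6.69-fold higher, while Hamp, which encodes the iron hormone hepcidin, was 18.3-fold and Batf, a transcription factor, 11.2-fold lower. Stromal markers gave 0 higher and 3 lower of 12. The comparison gave 368 genes higher and 284 lower of 10315, and quantile normalization turned this balance to 250 and 349 (56.4% and 41.7% higher). The number of higher genes was 597 with a signal floor of 50 and 224 with a floor of 200. The array labelled LPS 16 h was nearly as close to lipofected pIC 4 h as the closest pair of arrays were to each other, so these values and the next comparison are close to one another.

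Lipofected pIC at 4 h was compared with LPS 4 h to ask what double-stranded RNA delivered by transfection added to LPS. Most interferon genes measured were higher with lipofected pIC and most inflammatory cytokine genes were lower, while interferon-stimulated genes hardly differed. The array labelled LPS 16 h, whose label names no pIC, gave a similar pattern against LPS 4 h. Its medians were 1.48 for interferons, −1.56 for cytokines and 0.00 for interferon-stimulated genes. With lipofected pIC 4 h they were 1.34, −1.52 and −0.04. Those arrays were only 76 genes apart, so these differences are not assigned to the lipofected RNA. Of the 35 interferon-stimulated genes, 15 had signals under 15000 with LPS 4 h. Whether the signals of the brighter ones could rise further on the array was not tested. Ifnb1 was 2.53-fold higher (714 to 1806), and Ifna2 and Ifna4 were at least 6.41-fold and 4.11-fold higher, so that 4 of 5 measured interferon genes were higher and 0 lower. Of the 9 named on the array, those at the floor with LPS 4 h could be measured only where they were higher here. Of 18 cytokine genes 0 were higher and 12 lower. Il1a was 33.9-fold lower, Il1b 7.40-fold, Il12b 4.61-fold, Il6 4.05-fold and Tnf 3.63-fold, and Il10 was at least 19.3-fold lower. Chemokines gave 1 higher and 7 lower of 19, with Cxcl1 47.2-fold and Cxcl2 10.7-fold lower.

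The NF-kB feedback list gave 0 higher and 9 lower of 19, among them Nos2, the inducible nitric oxide synthase (8.83-fold), Dusp1, a MAP kinase phosphatase (6.15-fold), and Socs3, an inhibitor of cytokine signalling (5.01-fold). Maturation genes gave 0 higher and 3 lower of 19. The integrated stress response gave 1 higher and 3 lower of 38 with a median of −0.13. Slc7a11 was 3.01-fold and Ddit4, an inhibitor of mTORC1, 2.30-fold lower, and Sesn2, a stress-induced regulator of mTORC1, was 2.14-fold higher. Ppp1r15a had a signal of 2106 against 2494 with LPS alone, and Ddit3 746 against 724. Neither eIF2alpha kinases with phosphatase subunits (11), translation initiation factors (35), ribosomal proteins (43) nor endoplasmic reticulum chaperones (27) had any gene 2-fold apart. Proliferation genes gave 7 higher and 0 lower of 27 with a median of 0.81, above all random lists. Beyond the lists, Ccnd1 was 8.89-fold and Asb2 8.85-fold higher, and Hamp was 21.5-fold and Batf 14.2-fold lower.

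Granulocyte markers were 3 higher and 0 lower of 15 on the same array, and macrophage markers gave 2 higher and 2 lower of 19, with Ccr2 5.03-fold higher. Altogether 488 genes were higher and 322 lower of 10290. The balance turned to 325 and 384 under quantile normalization (60.2% and 45.8% higher), and 311 genes were higher with a floor of 200 and 317 with the mean over probe sets. The series holds no array with lipofectamine alone at 4 h, so the reagent and its RNA cargo were not separated at that time.

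Soluble pIC at 4 h was compared with LPS 4 h to ask what the same RNA did when added to the medium. On the array labelled soluble pIC 4 h, most cytokine, chemokine and maturation genes were lower than with LPS alone, and most interferon-stimulated genes were not. Cxcl1 was 182-fold lower (22318 to 123), Ptgs2 171-fold, Il12b 108-fold, Tnf 38.1-fold and Il6 27.5-fold. Il1a was at the floor, at least 116-fold lower. Cytokines gave 0 higher and 16 lower of 18, chemokines 0 and 15 of 19, maturation genes 0 and 14 of 20, and the NF-kB feedback list 0 and 15 of 19. Cd40 was 15.4-fold lower and Cd86 3.34-fold lower.

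Of 35 interferon-stimulated genes 1 was higher, 8 lower and 26 neither, with a median of −0.40. Cxcl10 was 4.84-fold lower, Oasl1 2.93-fold lower, and Oas3, which makes the activator of RNase L, 2.58-fold higher. Ifnb1 was 5.31-fold lower (714 to 134). Sensors of double-stranded RNA gave 3 higher and 3 lower of 19, with Mavs, the mitochondrial adaptor of RNA sensors, 5.92-fold higher. Genes of the integrated stress response were split, with 4 higher and 4 lower of 38. Sesn2 was 3.95-fold and Ddit3 2.26-fold higher, Slc7a11 was 8.24-fold lower, and Ppp1r15a stood under the threshold at 1.96-fold lower. Translation initiation factors gave 4 higher and 1 lower of 35, led by Eif4ebp2 (3.96-fold higher), and apoptosis regulators gave 4 and 8 of 23.

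Proliferation genes gave 23 higher and 0 lower of 27, with a median of 1.51 above all random lists. Mcm2 was at least 6.32-fold, Mcm7 4.81-fold and Aurkb 4.77-fold higher. Immediate early genes went both ways (6 higher and 5 lower of 17), with the transcription factors Egr2 6.33-fold and Egr1 5.16-fold higher. Lysosomal genes gave 3 higher and 0 lower of 20 and cholesterol synthesis genes 1 and 4 of 18. Asb2 (21.0-fold), Tmem154 (19.5-fold), Rab7b, a GTPase of late endosomes (19.4-fold), and Arrdc3, an arrestin-like protein (16.6-fold), led the higher genes. Stromal markers gave 0 higher and 9 lower of 12 on this array, with Postn, a matrix protein, 3.23-fold lower, and Ccr2 among the monocyte markers was 10.4-fold higher. There were 2017 genes higher and 820 lower of 10635, with a median of 0.27 over all genes. Quantile normalization gave 1316 and 1007, moved the share of higher genes from 71.1% to 56.7% and the median to 0.11, and the mean over probe sets gave 1335 higher.

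The form of delivery at 4 h was examined by setting lipofected against soluble pIC. Whether soluble pIC 4 h and LPS 4 h carry each other's labels stays open. Lipofected pIC 4 h stood only 76 genes from the array labelled LPS 16 h, and no array held lipofectamine alone at 4 h. The values below are therefore not assigned to the form of delivery. Most of the interferon, cytokine and chemokine genes measured were higher with lipofected pIC, and 0 were lower. Il12b was 23.5-fold, Ptgs2 24.0-fold, Ifnb1 13.4-fold, Tnf 10.5-fold and Il6 6.80-fold higher. Cytokines gave 10 higher and 0 lower of 14, chemokines 12 and 0 of 19, maturation genes 11 and 0 of 20, interferons 4 and 0 of 5, and interferon-stimulated genes 8 and 0 of 35. Ch25h, which makes the antiviral sterol 25-hydroxycholesterol, was 21.4-fold higher. Proliferation genes gave 0 higher and 6 lower of 26, and glycolysis and HIF targets 0 and 7 of 19, such as Bnip3 (4.05-fold) and Egln3, an oxygen-sensing hydroxylase (3.12-fold). The integrated stress response gave 1 higher and 2 lower of 36. Stromal markers gave 7 higher and 0 lower of 12. The totals were 490 higher and 972 lower of 10532 with a median of −0.19 over all genes, and 564 and 706 under quantile normalization (33.5% and 44.4% higher) with a median of −0.11. With the mean over probe sets 592 genes were lower.

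**Figure D2:**
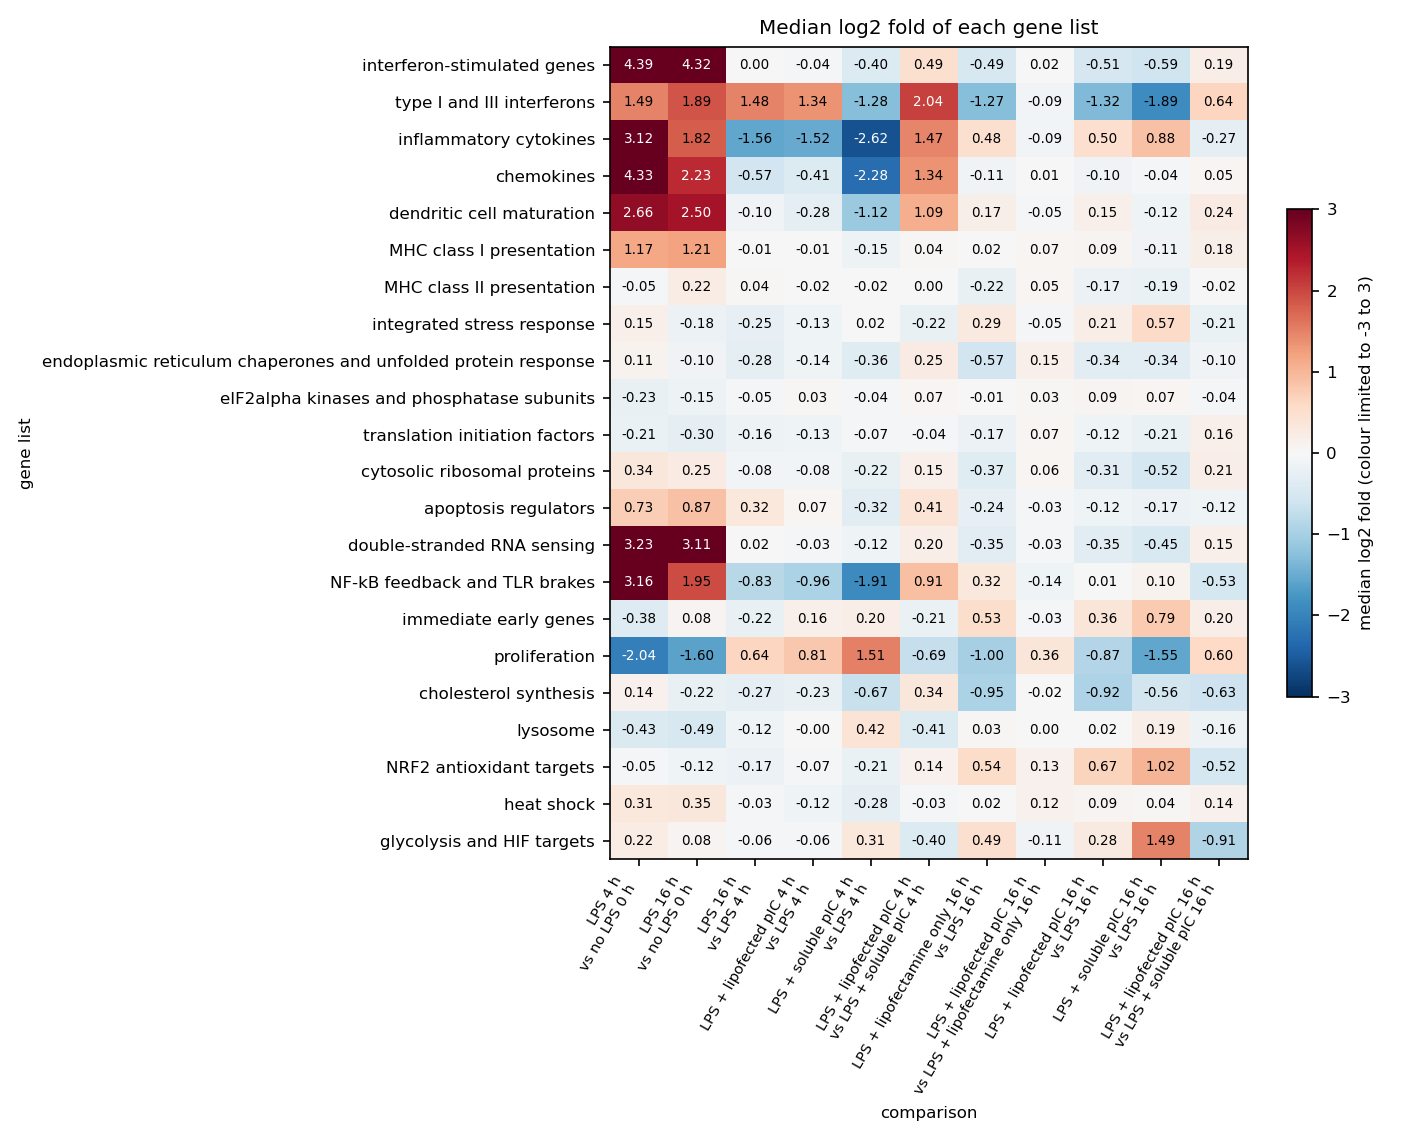
Median log2 fold of each of 22 gene lists (rows) in each of the 11 comparisons (columns), drawn as colour limited to between −3 and 3. For soluble pIC against LPS, the cytokine median was −2.62 at 4 h and 0.88 at 16 h and the proliferation median 1.51 and −1.55, the 16 h values against the array labelled LPS 16 h.

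At 16 h, lipofectamine only was compared with the array labelled LPS 16 h as the reagent without RNA. Some genes for interleukin-1, hypoxia and oxidative stress responses were higher on the lipofectamine only array, and many interferon, proliferation, cholesterol synthesis and macrophage genes were lower. Il1a was 4.78-fold, Osm, a cytokine of the interleukin-6 family, 4.76-fold and Il1b 3.50-fold higher, while Tnf was 4.28-fold lower. Cytokines gave 5 higher and 1 lower of 17, interferons 0 and 4 of 6, and interferon-stimulated genes 0 and 4 of 35. Ramp3, a receptor activity-modifying protein, was 17.3-fold higher (995 to 17259), and Stat4, a transducer of IL-12 signals, 9.68-fold higher.

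The integrated stress response gave 5 higher and 0 lower of 36. Trib3, a pseudokinase induced by ATF4, was 3.52-fold, Ddit4 3.44-fold, Ddit3 3.29-fold and Chac1, which degrades glutathione, 2.41-fold higher. Ppp1r15a had a signal of 3751 against 2439. Endoplasmic reticulum chaperones gave 1 higher and 4 lower of 27, with Sdf2l1 3.91-fold lower. Proliferation genes gave 0 higher and 14 lower of 27, with Cdc20 6.06-fold and Ccnb2, which encodes cyclin B2, 5.70-fold lower. Cholesterol synthesis genes gave 1 higher and 8 lower of 18, with Fdps 5.35-fold lower. Immediate early genes gave 7 higher and 0 lower of 17, glycolysis and HIF targets 6 and 0 of 19, and NRF2 targets 3 and 0 of 15. Macrophage markers gave 1 higher and 8 lower of 18 on this array. The complement genes C1qa (12032 to 1250, 9.63-fold) and C1qb (8.09-fold) were lower, as was Mrc1 (at least 12.3-fold). Conventional dendritic cell markers gave 1 and 5 of 14, stromal markers 0 and 5 of 12, and granulocyte markers 0 and 4 of 15. The comparison held 961 genes higher and 707 lower of 10570. Soluble pIC 16 h, given without the reagent, differed from the array labelled LPS 16 h in many of the same genes, since 488 genes were higher and 405 lower than that reference on all 3 other 16 h arrays.

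Lipofected pIC at 16 h was compared with lipofectamine only at 16 h, the sole comparison whose labels separate the RNA from its carrier. These were the closest arrays, and most of the gene groups that differed between treatments elsewhere had 0 genes 2-fold apart. With 1 array each and no technical repeat, a small effect of the RNA was not told apart from a wrong label or one RNA sample on both arrays. The values below are therefore not evidence that lipofected pIC lacks an effect. Of 35 interferon-stimulated genes 0 were 2-fold apart, with a median of 0.02 (percentile 0.87), and 0 were also 2-fold apart among 4 interferon genes, 17 cytokine genes, 36 genes of the integrated stress response and 19 sensors of double-stranded RNA. Ifnb1 had signals of 2420 and 2285, Il6 18900 and 18284, Ppp1r15a 3180 and 3751, and Ddit3 1894 and 2044.

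Proliferation genes had a median of 0.36, above all random lists, though 0 of 26 reached 2-fold and the furthest, Rrm2, a subunit of ribonucleotide reductase, was 1.82-fold higher. Among granulocyte markers on the same array 3 of 15 were higher, namely Elane (2.99-fold), Prtn3 (2.18-fold) and Mpo (2.05-fold), which encode proteins of neutrophil granules. Clec2d, a ligand of NK cell receptors, was 3.61-fold lower (3502 to 971), Rxra, a nuclear receptor, 2.47-fold lower, and Ldhb, a lactate dehydrogenase, 2.94-fold higher. Medians below 0 with low percentiles were those of glycolysis and HIF targets (−0.11, percentile 0.01), the NF-kB feedback list (−0.14, percentile 0.03, with 1 gene lower) and maturation genes (−0.05, percentile 0.13). In total 27 genes were higher and 24 lower of 10398. Quantile normalization gave 41 and 16 (52.9% and 71.9% higher), and signal floors of 50 and 200 changed the counts by more than 1.5 times. Without probe sets that may detect several transcripts or genes the balance turned the other way, to 21 higher and 42 lower. The mean over probe sets gave 13 and 16.

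Against the array labelled LPS 16 h, lipofected pIC 16 h gave values much like those of lipofectamine only, with which it shared that reference. Cytokines gave 5 higher and 1 lower of 15, interferons 0 and 4 of 6, interferon-stimulated genes 0 and 6 of 35, and NRF2 targets 6 and 0 of 15. Proliferation genes gave 0 higher and 11 lower of 26 and cholesterol synthesis genes 1 and 7 of 18. In the integrated stress response list there were 3 higher and 1 lower of 36. Ramp3 was 18.6-fold and Tspan13, a tetraspanin, 11.1-fold higher. Macrophage markers gave 1 higher and 8 lower of 18 and stromal markers 0 and 7 of 11. The counts were 953 genes higher and 651 lower of 10586, with 616 higher by the mean over probe sets.

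Soluble pIC at 16 h against the array labelled LPS 16 h compared RNA in the medium with LPS alone at the later labelled time. Most glycolysis and oxidative stress genes, and some of the integrated stress response and cytokine genes, were higher with soluble pIC, and most interferon, proliferation and granulocyte genes were lower. Il1a was 23.2-fold, Il1b 5.77-fold and Il10 at least 14.6-fold higher, and Ifnb1 was 14.3-fold lower (2035 to 142). Hmox1, the heme oxygenase induced by NRF2, was 11.7-fold higher (1850 to 21714). Adm, the hypoxia-induced peptide adrenomedullin, was 24.6-fold higher, and Hilpda, a hypoxia-induced lipid droplet protein, at least 83.4-fold higher.

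Cytokines gave 8 higher and 3 lower of 18, chemokines 5 and 6 of 19, interferons 0 and 5 of 6, and interferon-stimulated genes 0 and 9 of 35. The chemokines Cxcl1 (12.3-fold) and Cxcl3 (10.7-fold) were higher while Ccl12 (10.0-fold) and Cxcl9 (9.11-fold) were lower. Of 36 genes of the integrated stress response 12 were higher, 2 lower and 22 neither, with a median of 0.57 at percentile 99.9. Ddit4 was 7.57-fold, Trib3 4.98-fold, Ddit3 3.33-fold, Nupr1, a stress-induced chromatin protein, 3.04-fold, Atf3 2.97-fold and Atf4 2.66-fold higher. Lipofectamine only was also above the array labelled LPS 16 h for Ddit4, Trib3 and Ddit3, and for Ddit3 by nearly as much. Eif4ebp1, a repressor of cap-dependent translation, was 5.47-fold higher among initiation factors that gave 2 higher and 4 lower of 35. Ribosomal protein genes had a median of −0.52 (percentile 0.055), with 0 higher and 5 lower of 43. Glycolysis and HIF targets gave 11 higher and 0 lower of 19, including Egln3 (11.2-fold), Bnip3 (6.11-fold) and Vegfa, an angiogenic growth factor (5.05-fold). NRF2 targets gave 8 higher and 0 lower of 15, with Gclc, an enzyme of glutathione synthesis, 7.52-fold higher.

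Proliferation genes gave 1 higher and 16 lower of 27 with a median of −1.55, below all random lists. Cdc20 and Rrm2 were at least 11.5-fold and 11.1-fold lower. Granulocyte markers gave 1 higher and 11 lower of 15 on this array, such as Elane (at least 14.4-fold) and Mpo (10.4-fold), and mast cell markers 1 and 3 of 8. Macrophage markers gave 5 higher and 9 lower of 19, with Marco, a scavenger receptor, at least 25.7-fold higher and C1qa 14.9-fold lower. The counts were 1313 genes higher and 987 lower of 10670. With lipofectamine only 16 h as the reference, chosen after seeing the data because of the doubt about the array labelled LPS 16 h, they were 442 and 438. Of 142 named genes, 34 then stayed within 1.5-fold of their value, 97 moved and 11 reversed, so many of the folds above depend on the reference. The list medians nearer to 0 with that reference included cytokines (0.30 from 0.88), glycolysis (0.80 from 1.49), NRF2 targets (0.52 from 1.02), the integrated stress response (0.14 from 0.57) and ribosomal proteins (−0.15 from −0.52). Proliferation genes moved to −0.45 from −1.55, interferons to −0.79 from −1.89, interferon-stimulated genes to −0.19 from −0.59 and granulocyte markers to −1.21 from −2.15. The sign turned for immediate early genes (−0.29 from 0.79), cholesterol synthesis (0.47 from −0.56), endoplasmic reticulum chaperones (0.33 from −0.34), stromal markers (0.16 from −0.81), class II presentation (0.09 from −0.19) and apoptosis regulators (0.08 from −0.17).

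The form of delivery at 16 h was examined in the same way, without the array labelled LPS 16 h. Lipofectamine only, which carried no RNA, stood 880 genes apart from soluble pIC 16 h, against 1019 for lipofected pIC. The values below therefore do not separate the reagent from the form in which the RNA was given. Some glycolysis, cytokine and oxidative stress genes were lower with lipofected than with soluble pIC, and interferon beta, 10 of 26 proliferation genes and most granulocyte markers were higher. Ifnb1 was 17.0-fold higher (142 to 2420), and Il10 was at least 14.6-fold, Il1a 5.16-fold and Hmox1 4.74-fold lower. Nos2 was 11.1-fold and Ptgs2 5.25-fold lower in the NF-kB feedback list, which gave 1 higher and 5 lower of 19. Arg1, the arginase of alternatively activated macrophages, was at least 49.1-fold lower, Fabp4, a fatty acid carrier, 20.1-fold and Adm 16.6-fold lower.

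The integrated stress response gave 0 higher and 5 lower of 36, including Aldh1l2, an enzyme of mitochondrial folate metabolism (at least 5.57-fold), Vldlr, a lipoprotein receptor (5.36-fold), and Ddit4 (4.34-fold). Glycolysis and HIF targets gave 0 higher and 7 lower of 19, and NRF2 targets 0 and 3 of 15. Interferon-stimulated genes gave 0 and 0 of 35, with a median of 0.19. Proliferation genes gave 10 higher and 1 lower of 26. Granulocyte markers gave 11 higher and 0 lower of 15, with Elane at least 14.5-fold and Prtn3 8.97-fold higher, and mast cell markers 4 and 0 of 8, with Ms4a2, a chain of the IgE receptor, 6.00-fold higher. In all 514 genes were higher and 505 lower of 10563, with 339 higher by the mean over probe sets.

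**Figure D3:**
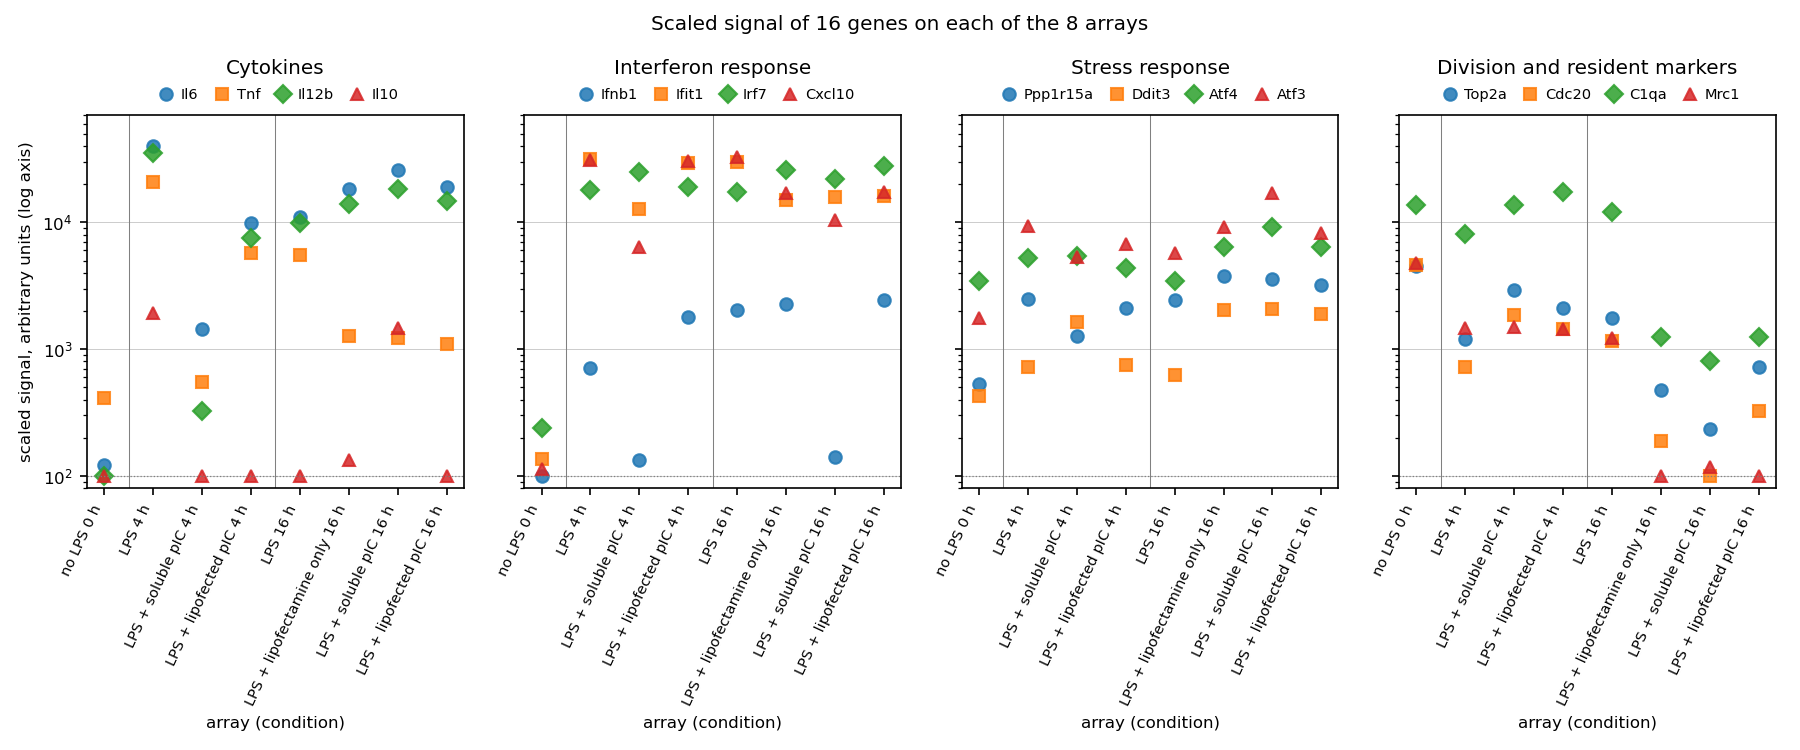
Scaled signal (log axis) of 16 genes on the 8 arrays, with 1 point per gene and array and values under the floor of 100 drawn at 100. Il6 reached 40004 with LPS 4 h and 1454 with soluble pIC 4 h, and Ppp1r15a lay between 531 without LPS and 3751 with lipofectamine only 16 h.

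The pair of comparisons of lipofected with soluble pIC shared no array, so their gene lists could be set against each other. At both times the lipofected arrays also carried the reagent, so genes shared between the times may reflect lipofectamine as well as the RNA. Both times had 66 genes higher with lipofected pIC, against 23.1 for independent lists of these sizes, and 108 genes lower, against 43.6. In opposite directions there were 37 genes higher at 4 h and lower at 16 h (21.6) and 45 the reverse (46.6). Another pair without a shared array was LPS 4 h against no LPS and soluble pIC 16 h against lipofectamine only. Of genes higher in the former, 83 were higher (45.4) and 107 lower (44.9) in the latter. Of genes lower in the former, 139 were higher (109.0) and 83 lower (108.0). Counts for independent lists can thus be exceeded in opposite directions at once, and are not a level without a shared effect. Soluble pIC against LPS gave 480 genes higher at both times (251.0 for independent lists) and 217 lower at both (77.8), with 196 higher at 4 h and lower at 16 h (192.0) and 132 the reverse (102.0). The references of that pair, LPS 4 h and the array labelled LPS 16 h, were themselves close, with 652 genes apart. The same direction is therefore partly built into it, and the counts for independent lists are not its level without an effect. Lipofected pIC against LPS gave 45 genes higher at both times (43.1) and 19 lower at both (20.1). In that last pair 102 genes were higher at 4 h and lower at 16 h (31.9) and 77 the reverse (27.2). The array labelled LPS 16 h nearly equalled lipofected pIC 4 h, so opposite directions are built into that pair and the counts for independent lists are not its level without a difference.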

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

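All tests in this part were chosen after the results they concern had been seen, and the differences between times were not tested because each condition had 1 array.

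Several gene groups went opposite ways at 4 h and 16 h under the same comparison of labels. With soluble pIC against LPS, inflammatory cytokine genes had a median log2 fold of −2.62 at 4 h and 0.88 at 16 h, a difference of 3.50. Proliferation genes in that comparison had 1.51 and −1.55, a difference of −3.06. With lipofectamine only as the 16 h reference, chosen after seeing the data, the 16 h medians were 0.30 for cytokines and −0.45 for proliferation genes. With lipofected pIC against LPS, interferon genes had 1.34 and −1.32, a difference of −2.66, and proliferation genes 0.81 and −0.87, a difference of −1.68. Against lipofectamine only, lipofected pIC 16 h had medians of −0.09 for interferon genes and 0.36 for proliferation genes, so the proliferation median then had the same sign as at 4 h and the interferon median was near 0. All of these 16 h values have the array labelled LPS 16 h as their reference unless stated, and its label is in doubt. That array nearly equalled lipofected pIC 4 h, with 76 genes apart, so opposite signs at the times are built into the comparison of lipofected pIC with LPS.

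The array labelled LPS 16 h stood closer to lipofected pIC 4 h than to the other 16 h arrays. Over 24 genes at least 4-fold apart between the other 4 h and 16 h arrays with LPS, chosen without it and lipofected pIC 4 h, its median position was 0.04 on a scale from the 4 h arrays (0) to the 16 h arrays (1), and all 24 put it nearer to 4 h, which is consistent with a wrong time or condition on its label. One RNA sample on both this array and lipofected pIC 4 h stays open, because 76 genes separated them against 51 in the closest pair and no technical repeat sets the noise. Their 5′ signals for 18S ribosomal RNA differed, 3297 against 18864, but this rests on 1 control probe set and its cause was not tested. A biological account also stays open, in which lipofectamine and soluble pIC each moved the cells the same way by 16 h. It cannot be told apart from a wrong label here, since the 893 genes that differed alike on all 3 other 16 h arrays share 1 reference.

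On the array labelled soluble pIC 4 h, interferon-stimulated genes were high while inflammatory cytokine genes were low. A share of cells that did not respond to LPS stays open, because secreted interferon could raise interferon-stimulated genes in those cells too. Interferon-stimulated genes kept a median of 72.3% of their increase with LPS 4 h and cytokine genes 1.39%, 70.9 percentage points apart, with quartiles of 47.9% to 86.7% and 0.672% to 3.34%. Among genes with signals under 15000 on LPS 4 h, 15 interferon-stimulated and 11 cytokine genes, the medians were 85.2% and 1.39%. These percents restate the pattern and cannot decide whether a share of cells failed to respond. If the kept cytokine signal tracked the responding cells, 1.39% would leave few of them. A repeat of the no LPS sample was argued against by a median log2 fold of 4.12 for interferon-stimulated genes over no LPS. Exchanged labels of LPS 4 h and soluble pIC 4 h stay open. Both labels name LPS, however, so an exchange would move the low cytokine genes to LPS alone and would not account for them. An exchange cannot be told apart from an untested effect of soluble pIC on the response to LPS, which the design names. Neither of 2 gene sets decided whether the labels were exchanged. The 54 genes at least 4-fold higher on soluble pIC 16 h than on both lipofection 16 h arrays had a median of −0.71 between the arrays, with quartiles of −1.97 to 0.50. The 41 genes at least 4-fold lower there had 0.29, with quartiles of −0.95 to 0.83. Soluble pIC against LPS shared more genes in the same direction at both times than independent lists would (480 against 251.0 higher, 217 against 77.8 lower). That count cannot decide it either, because the references LPS 4 h and the array labelled LPS 16 h were close (652 genes apart). Sharing in the same direction is thus partly built in, and the label of the 16 h reference is in doubt.

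Among the 10092 probe sets with no single gene name, which entered no comparison of genes, 252 were at least 2-fold lower on lipofected pIC 16 h than on lipofectamine only and 6 were higher, whereas named genes gave 24 and 27. Noise of dim probe sets was argued against, since 21.6% of unnamed probe sets with signals of 200 to 500 were lower against 0.257% of probe sets chosen for genes. The latter were picked as the brightest of each gene. Of the further probe sets of named genes in that range, 3.16% were lower. A lowering of these RNAs by lipofected pIC at both times stays open. On lipofected pIC 4 h the same 252 had a median log2 of 0.20 over soluble pIC 4 h, with quartiles of −0.18 to 0.68. Over LPS 4 h the median was 0.99 with quartiles of 0.52 to 1.5, which goes against a lowering. LPS 4 h was itself low in these probe sets, however, and the series holds no lipofectamine only array at 4 h. Less unspliced or nuclear RNA in the lipofected pIC 16 h sample is a candidate explanation, since 169 of 16752 further probe sets of named genes were lower and 25 higher. All 6 probe sets of Malat1 with a mean signal over 200 were lower too, with a median of −0.81. Malat1 is a nuclear RNA chosen after its values were seen. LPS 4 h was as low, with a median log2 signal of 7.05 over the 252 probe sets against 7.17 and a brightest Malat1 signal of 949 against 1216, and whether treatment or preparation made the difference was not tested.

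The control probe set for the 5′ part of 18S ribosomal RNA had a signal of 35820 on LPS 4 h and 3297 on the array labelled LPS 16 h, a 10.9-fold range across arrays, while the 3′ probe set of that RNA ranged 1.41-fold, from 839 to 1179. The 5′ signal was nearly as low on lipofectamine only 16 h (3663).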

How the results depend on the processing

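The alternatives were fixed in advance except the lipofectamine only reference, which was chosen after seeing the data. The values as deposited differ from the main ones by 1 factor for all arrays, so that alternative could move nothing and says nothing about stability. Across the other 5 settings fixed in advance the lists' medians were within 1.5-fold of the main value in 315 of 319 cases with a floor of 200, 324 of 328 with a floor of 50, 326 of 328 with the mean over probe sets, 327 of 328 with quantile normalization and 320 of 328 without shared probe sets, and 0 of the medians of at least 1 in size changed sign. Values of single genes moved by more in 237 of 1555 cases with a floor of 200, 92 with a floor of 50, 158 with the mean over probe sets, 2 with quantile normalization and 77 of 1354 without shared probe sets. Of named genes at least 2-fold apart, the sign reversed in 1 case under quantile normalization and 2 without shared probe sets. No paired analysis was made, each condition having 1 array, and folds of genes near the floor are limited by signal over background.

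Quantile normalization moved 4 of 22 counts. LPS 4 h against no LPS then had 1775 lower genes, lipofected pIC 4 h against LPS 4 h 325 higher, soluble pIC 4 h against LPS 4 h 1316 higher, and lipofected pIC 16 h against lipofectamine only 41 higher. E2f5 reversed to 0.89 in lipofected against soluble pIC 4 h. With a floor of 50, which admits dimmer genes, LPS 16 h against LPS 4 h had 597 higher genes and lipofected pIC 16 h against lipofectamine only 132 higher and 115 lower. With a floor of 200 these were 224, 10 and 12, and lipofected pIC 4 h against LPS 4 h had 311 higher. With the mean over probe sets, higher genes numbered 317 for lipofected and 1335 for soluble pIC 4 h against LPS 4 h, 13 for lipofected pIC 16 h against lipofectamine only, 616 against LPS 16 h and 339 against soluble pIC 16 h, and 592 were lower for lipofected against soluble pIC 4 h. Without shared probe sets, 42 genes were lower for lipofected pIC 16 h against lipofectamine only. Pfkl reversed to 0.26 in lipofected against soluble pIC 4 h and Eef2k to −0.11 in lipofected pIC 16 h against lipofectamine only. Apart from the floors, the cause was not tested.

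With lipofectamine only as the reference for soluble pIC 16 h, the counts were 442 higher and 438 lower, 21 of 30 list medians stayed within 1.5-fold and 9 moved. Of the 9, immediate early genes (−0.29), cholesterol synthesis (0.47), endoplasmic reticulum chaperones (0.33) and stromal markers (0.16) changed sign. Of 142 named genes only 34 stayed within 1.5-fold, while 97 moved and 11 reversed. The reversals, counted among genes at least 2-fold apart, were Sdf2l1 (0.80), Eif3i (0.10), Nr4a2 (−0.42), Fos (−0.32), Fdps (0.82), Sqle (0.25), Mgl2 (0.11), Clec10a (0.15), Mrc1 (0.23), Postn (0.16) and Col3a1 (0.54). The cause was not tested.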

Other observations

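No test in this part was run; the values are described only. Elane, Mpo and Prtn3, which encode granule proteins of neutrophil precursors, differed between the 16 h arrays. Lipofected pIC 16 h was above lipofectamine only by 2.99-fold for Elane, 2.05-fold for Mpo and 2.18-fold for Prtn3, and soluble pIC 16 h was below the array labelled LPS 16 h by at least 14.4-fold for Elane, 10.4-fold for Mpo and 10.3-fold for Prtn3. With lipofectamine only as the reference, the granulocyte and mast cell marker lists had medians of −1.21 and −1.09 on soluble pIC 16 h.

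Eif2ak2, which encodes PKR, had a signal of 472 without LPS, 4500 with LPS 4 h, 4345 with lipofected pIC 4 h and 2459 with soluble pIC 4 h. The signals at 16 h were 4076 on the array labelled LPS 16 h, 2074 with soluble pIC, 2019 with lipofected pIC and 2487 with lipofectamine only. Ppp1r15a was above its signal of 531 without LPS on every other array, with 1272 the lowest (soluble pIC 4 h) and 3751 the highest (lipofectamine only 16 h).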
